A study of Rattus norvegicus with 36 samples.

How the data were processed

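Gene expression was measured on 36 single-colour oligonucleotide arrays hybridised with biotin-labelled cRNA from female Sprague-Dawley rats, 33 arrays of mammary cancers and 3 of normal mammary tissue. Per the labels, total RNA was taken with acid guanidine, phenol and chloroform and cleaned on silica membranes, its quality was checked on a gel, and 8 µg was used for the cRNA. The deposited table holds 1 intensity per probe set and array, on a linear scale. The method that summarised the probes and scaled the arrays is not given in the sources used here. In the values themselves, the mean of each array after leaving out 2% of the probe sets at each end was about 500, so every array had been scaled as a whole. Values ran from 0.0151 to 32544, and the median intensity of an array lay between 161.4 and 222.7. Arrays carry no count of molecules, so precision rests on the number of arrays, the spread between them and the signal over background.

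Every array was placed in its group by its label alone, which gave 10 groups. The labels do not say that each cancer came from a different rat, and they give no batch or date of hybridisation. The p-values therefore measure the spread between these samples. No array was left out of the fit used for the values below, and no pair of arrays was identical (highest correlation 0.981). The correlation between arrays of the same group ran from 0.885 to 0.972.

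Of the 31099 probe sets, 20832 carried exactly 1 gene symbol in the table of probe sets used (14218 symbols), 436 carried several and 9831 carried none. Of the 20832, 20764 had a gene identifier that the RefSeq gene table also lists. Intensities were transformed as log2(intensity + 42.8), the added constant being the 20th percentile of all values. On this scale fold changes of weakly expressed genes are smaller than on the raw scale. The medians of the arrays lay within 0.46 on the log2 scale (7.33 to 7.80), under the limit of 0.5 set for adding a normalization, so none was added. A probe set was kept where it exceeded 125.8, the 40th percentile of all values, on at least 3 arrays. For each symbol the probe set with the highest mean over all arrays was taken, which left 11773 genes. No chromosome positions are given, since the genome build behind the probe sets is not stated.

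A model with 1 mean per group was fitted to all 36 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), and p-values were adjusted over the 11773 genes by the Benjamini-Hochberg method, with adjusted p under 0.05 taken as the threshold. The PhIP group with H-ras mutation holds 1 array, which added to the mean of the cancers and to no other comparison. Contrasts were the 33 cancers against the 3 normal tissues, H-ras mutated against nonmutated cancers as the mean of the MNU and the radiation plus MNU differences, each of these alone, their difference (the interaction), an F test over the 6 groups of nonmutated cancers, each induced nonmutated group against the spontaneous cancers, combined treatment against the chemical alone, and radiation against no radiation with equal weight in 4 backgrounds. Values are group means ± SD over arrays, and log2 fold changes ± SE from the fit. A contrast of the spontaneous cancers with the other 19 nonmutated cancers was added after the results had been seen.

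The genes named here come from a set given by a rule, and not every gene of that set is printed. In a comparison with any gene past the threshold, the set held the 10 largest rises and 10 largest falls among these genes. Elsewhere it held the 3 genes with the smallest unadjusted p, as values. In the 3 comparisons tested with gene lists, up to 4 members of each list with the smallest adjusted p were added. Hras itself was to be named in every comparison, but no probe set carried its symbol in the table used, so it was not analysed here. Some other list members were not analysed here either.

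The 23 gene lists had 303 members, of which 258 were measured: luminal epithelial, basal and myoepithelial, milk proteins and lactation, hormone response, cell cycle, RAS-MAPK output, p53 targets, DNA repair, xenobiotic metabolism, fatty acid synthesis, cholesterol synthesis, interferon response, mesenchymal transition, adipocyte, fibroblast and matrix, endothelial, T and NK cell, B and plasma cell, macrophage, mast cell, skeletal muscle, brown fat, and candidate cancer genes. Each was tested with camera, which compares the list with all other genes, at a preset correlation of 0.01 between genes and again with the correlation estimated from the data, for the cancers against normal tissue, for H-ras mutation and for radiation. List p-values were adjusted over the 23 lists. The H-ras interaction was tested with the same lists after the gene results had been seen. Also added later were two-sided permutation tests of the list means, with array labels permuted within backgrounds (all 15876 arrangements for H-ras, 1e+05 random ones for radiation).

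The contrasts, gene lists, naming rule, filter, constant and most of the other settings tried were fixed before the data were examined. The settings fixed in this way were quantile normalization, no filter, a stricter filter (326.9, the 60th percentile), an added constant of 7.05 or 125.8 (5th and 40th percentile), all filtered probe sets (16370), the mean of a gene's probe sets, a fit of only the groups compared, a trended and robust variance, the replicate number as a block, each array left out, and camera with the estimated correlation. Chosen after seeing the data were leaving out the array with the lowest RNA quality, and fitting the signal ceiling of each array (the mean log2 intensity of its 50 brightest probe sets) as a covariate or as a block. For the block, arrays were divided at the highest ceiling of the spontaneous cancers, so this division was not independent of that group. For the spontaneous genes, the ceiling as an explanation was first judged by the covariate and the block, which left it undecided. That rule was replaced by a comparison of lower-ceiling with other arrays within the other groups, and the limits of the new rule were set after its values had been seen. A covariate for skeletal muscle markers was also fitted.

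The fit was tested on simulated data in which 200 of 11773 genes were changed by 1 or 2 on the log2 scale. For the cancers against normal tissue it recovered 83% and 96% of them, and 7.3% of its calls were unchanged genes. For H-ras it recovered 94% and 100% (4% false), for the F test over etiologies 72% and 94% (4% false), and for radiation over 4 backgrounds 98% and 100% (5.7% false). For radiation against spontaneous cancers the shares were 74% and 94% (5.6% false). A simulated shift of 1 in the macrophage list gave an adjusted p of 6.31e-36 with camera at the preset correlation, and no other list passed. The simulated genes were independent of each other, so this does not show how often lists of correlated genes pass by chance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.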

Results

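Expression was profiled in 33 rat mammary cancers and 3 normal mammary tissues, to set cancers of different causes, with and without an H-ras mutation, beside each other. The cancers comprised 3 spontaneous ones from untreated rats and 4 after whole-body gamma radiation (1 Gy). A further 9 followed the alkylating agent MNU (methylnitrosourea, 40 mg/kg), 5 with and 4 without an H-ras mutation. PhIP, a mutagen formed when meat is cooked, preceded 4 (1 mutated, 3 nonmutated). The rest were 9 after radiation and MNU (5 mutated, 4 nonmutated) and 4 nonmutated ones after radiation and PhIP. Rats were treated at 7 weeks of age, the chemical followed radiation after 3 days, and all ate a diet with 23.5% corn oil from 9 weeks. The 3 normal tissues came from untreated rats. The leading principal component held 22.8% of the variance and separated normal tissue (scores of at least 56.6) from the cancers (at most 21.6).

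The first comparison asked how the cancers differ from normal mammary tissue. Genes of fat cells were far lower in the cancers, while an epidermal growth factor receptor ligand, the prolactin receptor and the matrix proteases Mmp13 and Mmp3 were far higher. Fabp4, the fatty acid binding protein of adipocytes, measured 7.44 ± 0.89 (SD, n = 33) in the cancers and 13.78 ± 0.24 (SD, n = 3) in normal tissue, a log2 fold change of −6.34 ± 0.44 (SE) (limma adjusted p = 5.29e-12). Areg, which encodes the receptor ligand amphiregulin, measured 12.69 ± 0.50 against 8.31 ± 0.38, a rise of 4.39 ± 0.30 (adjusted p = 2.51e-12). Prlr, the prolactin receptor, rose by 3.46 ± 0.44 (adjusted p = 8.13e-07). Each of these 3 genes lay on the same side of all normal tissues in 33 of 33 cancers.

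In all, 4045 of 11773 genes passed the threshold, 2121 higher and 1924 lower in the cancers, and 987 of them changed at least 2-fold (455 higher, 532 lower). The other large rises were those of Gp2, a membrane glycoprotein of secretory granules (4.93 ± 0.51, adjusted p = 2.42e-08), Mup5, of the major urinary protein family (4.79 ± 0.78, adjusted p = 2.64e-05), the collagenase Mmp13 (3.94 ± 0.60, adjusted p = 1.1e-05) and the transcription factor Tfap2b (3.56 ± 0.46, adjusted p = 8.38e-07). They were followed by the stromelysin Mmp3 (3.54 ± 0.54, adjusted p = 1.19e-05), the orphan receptor Gpr37 (3.35 ± 0.20, adjusted p = 2.33e-13), Nxpe2 (3.33 ± 0.32) and the tight junction gene Cldn6 (3.22 ± 0.30). The probe sets of Mup5, and those of Obp3 and Hbb named further on, are of a kind that can bind several members of a gene family. Large falls included Car3, a carbonic anhydrase abundant in fat (−5.19 ± 0.41), Saa3, an acute phase protein (−5.13 ± 0.93), the water and glycerol channel Aqp3 (−5.13 ± 0.40), the lipid droplet protein Cidec (−5.07 ± 0.18, adjusted p = 6.34e-19) and Pck1, which makes glycerol precursors for fat (−4.89 ± 0.15, adjusted p = 2.13e-20). So did the fatty acid transporter Cd36 (−4.70 ± 0.51), Ces1d (−4.66 ± 0.28), Plin1, which coats lipid droplets (−4.57 ± 0.20), and the fat hormone Adipoq (−4.52 ± 0.19, adjusted p = 5.44e-17). For every one of these genes, all 33 cancers lay on the same side of all 3 normal tissues.

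**Figure D1:**
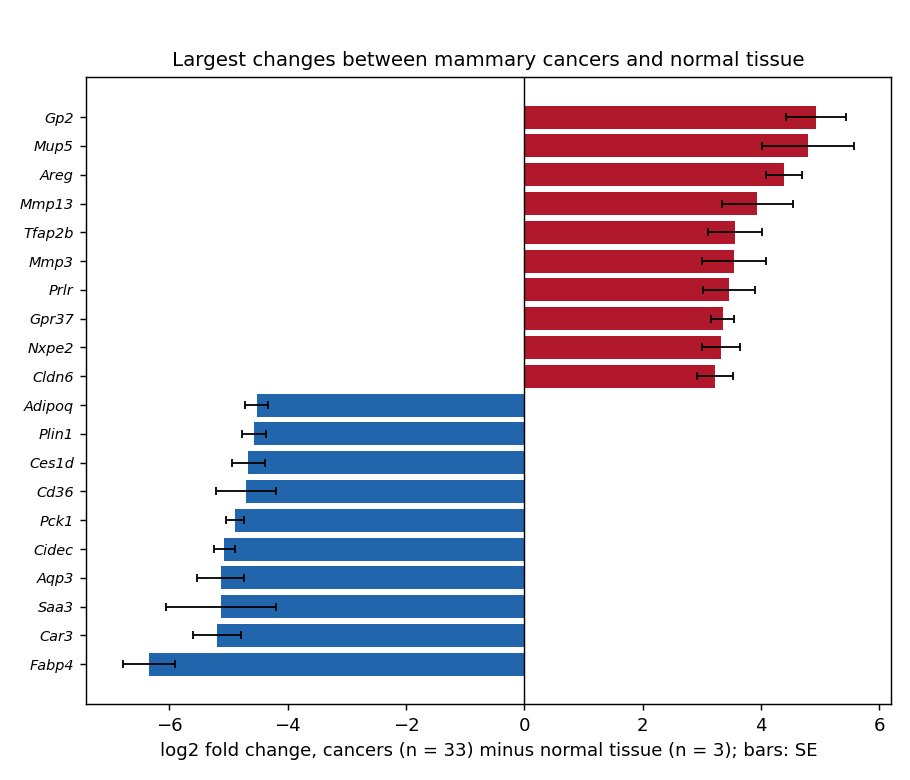
Horizontal bars give the log2 fold change of the 10 largest rises and the 10 largest falls in the 33 cancers against the 3 normal mammary tissues, with SE bars from limma. Fabp4 reaches −6.34 and Gp2 reaches 4.93.

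Of 13 adipocyte markers, 12 fell and none rose (adjusted p = 2.34e-20 with camera, 0.000192 with an estimated correlation), and this was the only list still called with the estimated correlation. The list mean was 8.10 ± 0.24 (SD, n = 33) in the cancers and 11.14 ± 0.36 (SD, n = 3) in normal tissue, and Aqp7 fell by 2.78 ± 0.12. Among 10 genes of fatty acid synthesis, 8 fell, such as the desaturase Scd (−3.49 ± 0.56), the carboxylase Acaca (−1.24 ± 0.18) and the acetyl-CoA maker Acss2 (−1.68 ± 0.25), while the elongase Elovl6 rose by 1.28 ± 0.24. The list had adjusted p = 0.00215, and adjusted p = 0.201 with an estimated correlation. Both measured brown fat genes were lower, Cidea by −3.51 ± 0.39 past the threshold and Cpt1b not past it (0 higher and 2 lower adjusted over the list alone). Together they had adjusted p = 0.0389, and adjusted p = 0.195 with an estimated correlation. Endothelial markers were lower too, 8 of 9 having fallen, among them the receptor Tek (−1.79 ± 0.27), Eng (−1.49 ± 0.24), Emcn (−1.54 ± 0.26) and Esam (−0.96 ± 0.16). Their list had adjusted p = 0.000252, and adjusted p = 0.195 with an estimated correlation.

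Epithelial genes moved in both directions. Of 14 luminal markers, 8 rose, such as the claudin Cldn7 (1.35 ± 0.22), the keratin Krt7 (1.89 ± 0.43), Spdef (1.27 ± 0.38) and the luminal regulator Gata3 (0.50 ± 0.17), and 1 fell. As a list they had adjusted p = 0.0534, and adjusted p = 0.476 with an estimated correlation. Of 12 basal and myoepithelial markers, 3 rose, namely Tp63 (1.37 ± 0.23), Krt15 (1.64 ± 0.30) and Krt5 (0.76 ± 0.15), and the oxytocin receptor Oxtr fell by 2.99 ± 0.22. The basal list had adjusted p = 0.656, and adjusted p = 0.896 with an estimated correlation. Of 8 milk genes, 4 fell, Glycam1 (−3.54 ± 1.28), Lpo (−2.65 ± 0.65), the whey protein Wap (−2.57 ± 0.94) and Xdh (−1.53 ± 0.46). The milk list had adjusted p = 0.0318, and adjusted p = 0.476 with an estimated correlation. Hormone response genes included 4 that rose, with Areg, Prlr and the progesterone-regulated Wnt4 (2.93 ± 0.37) among them, and 2 of 11 that fell, such as the growth hormone receptor Ghr (−2.33 ± 0.26). Adjusted over the list alone, 4 were higher and 3 lower, and the list had adjusted p = 0.186, and adjusted p = 0.476 with an estimated correlation. The mesenchymal transition list held 1 of 8 that rose, Twist1 (0.93 ± 0.31), and 3 that fell, Vim (−0.88 ± 0.19), Zeb2 (−1.06 ± 0.31) and Zeb1 (−0.70 ± 0.22). It had 2 higher and 3 lower adjusted over the list alone, with adjusted p = 0.495, and adjusted p = 0.751 with an estimated correlation.

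The growth and signalling lists held more genes that rose than genes that fell. Of 23 cell cycle genes, 8 rose and none fell, such as the topoisomerase Top2a (0.97 ± 0.29), the replication licensing genes Mcm2 (0.82 ± 0.25) and Mcm6 (0.86 ± 0.29) and the checkpoint kinase Bub1b (0.94 ± 0.32). Cell cycle genes had adjusted p = 0.00215, and adjusted p = 0.593 with an estimated correlation. Of 18 genes of RAS-MAPK output, 9 rose and 3 fell (11 and 3 adjusted over the list alone). The feedback inhibitors Spry1 (1.31 ± 0.13) and Spry2 (1.27 ± 0.20), the factor Etv5 (1.94 ± 0.32) and the receptor ligand Tgfa (1.27 ± 0.23) were among the rises, and the list had adjusted p = 0.00235, and adjusted p = 0.195 with an estimated correlation. Of 13 p53 targets, 6 rose and 1 fell (7 and 1 adjusted over the list alone). Risen p53 targets were the kinase Plk2 (1.40 ± 0.14), Perp (1.34 ± 0.17), Zmat3 (0.67 ± 0.12) and the cell cycle inhibitor Cdkn1a (1.5 ± 0.29), among others (adjusted p = 0.0179, and adjusted p = 0.195 with an estimated correlation). DNA repair genes held 4 of 14 that rose, Msh6 (0.87 ± 0.13), Apex1 (0.60 ± 0.12), Brca2 (1.14 ± 0.23) and Lig1 (0.61 ± 0.13), and 1 that fell (adjusted p = 0.276, and adjusted p = 0.703 with an estimated correlation). Of 9 candidate cancer genes, 4 rose, including the cell cycle inhibitors Cdkn2a (3.18 ± 0.51) and Cdkn2b (1.79 ± 0.27) and the cyclin Ccnd1 (1.19 ± 0.23), and 2 fell, including the tumour suppressor Rb1 (−1.65 ± 0.29). These genes had adjusted p = 0.287, and adjusted p = 0.593 with an estimated correlation. Xenobiotic metabolism held 1 of 7 genes that fell, Tiparp (−0.70 ± 0.19; adjusted p = 0.201, and adjusted p = 0.407 with an estimated correlation). Cholesterol synthesis held 1 of 11 that rose, the epoxidase Sqle (1.70 ± 0.43; adjusted p = 0.656, and 0.914 with an estimated correlation).

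Most immune markers past the threshold were lower in the cancers. Of 12 macrophage markers, 6 fell and none rose, such as Cd68 (−1.12 ± 0.28), Tyrobp (−0.85 ± 0.22), the lysozyme Lyz2 (−0.73 ± 0.21) and Csf1r (−0.64 ± 0.23). Adjusted over the list alone 7 were lower, with adjusted p = 0.0318 for the list, and adjusted p = 0.563 with an estimated correlation. Of 6 B and plasma cell markers, the antibody joining chain Jchain (−3.26 ± 0.79) and Mzb1 (−0.93 ± 0.29) fell (adjusted p = 0.0874, and 0.476 with an estimated correlation). Interferon genes went both ways, 2 of 13 higher and 3 lower, with the proteasome subunit Psmb9 at 1.52 ± 0.15 and the chemokine Cxcl10 at −1.21 ± 0.20 (adjusted p = 0.916, and 0.968 with an estimated correlation). None of 11 T and NK cell (adjusted p = 0.233, and 0.751 with an estimated correlation), 9 mast cell (0.468, and 0.847) or 11 skeletal muscle markers (0.867, and 0.968) passed. Those nearest the threshold were Prf1 at −0.66 ± 0.28, Tpsb2 at 1.45 ± 0.84 and Actn3 at 0.77 ± 0.35. Fibroblast and matrix genes held 1 of 15 that rose, Col5a2 (0.62 ± 0.15), and 2 that fell, Fbn1 (−0.89 ± 0.29) and Pdgfra (−1.21 ± 0.40). Their list had adjusted p = 0.201, and adjusted p = 0.751 with an estimated correlation. The mean and the median change had opposite signs for the interferon list (−0.07 and 0.01) and the skeletal muscle list (−0.01 and 0.13). Counts adjusted over the list alone equalled the counts given wherever no other is stated.

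**Figure D2:**
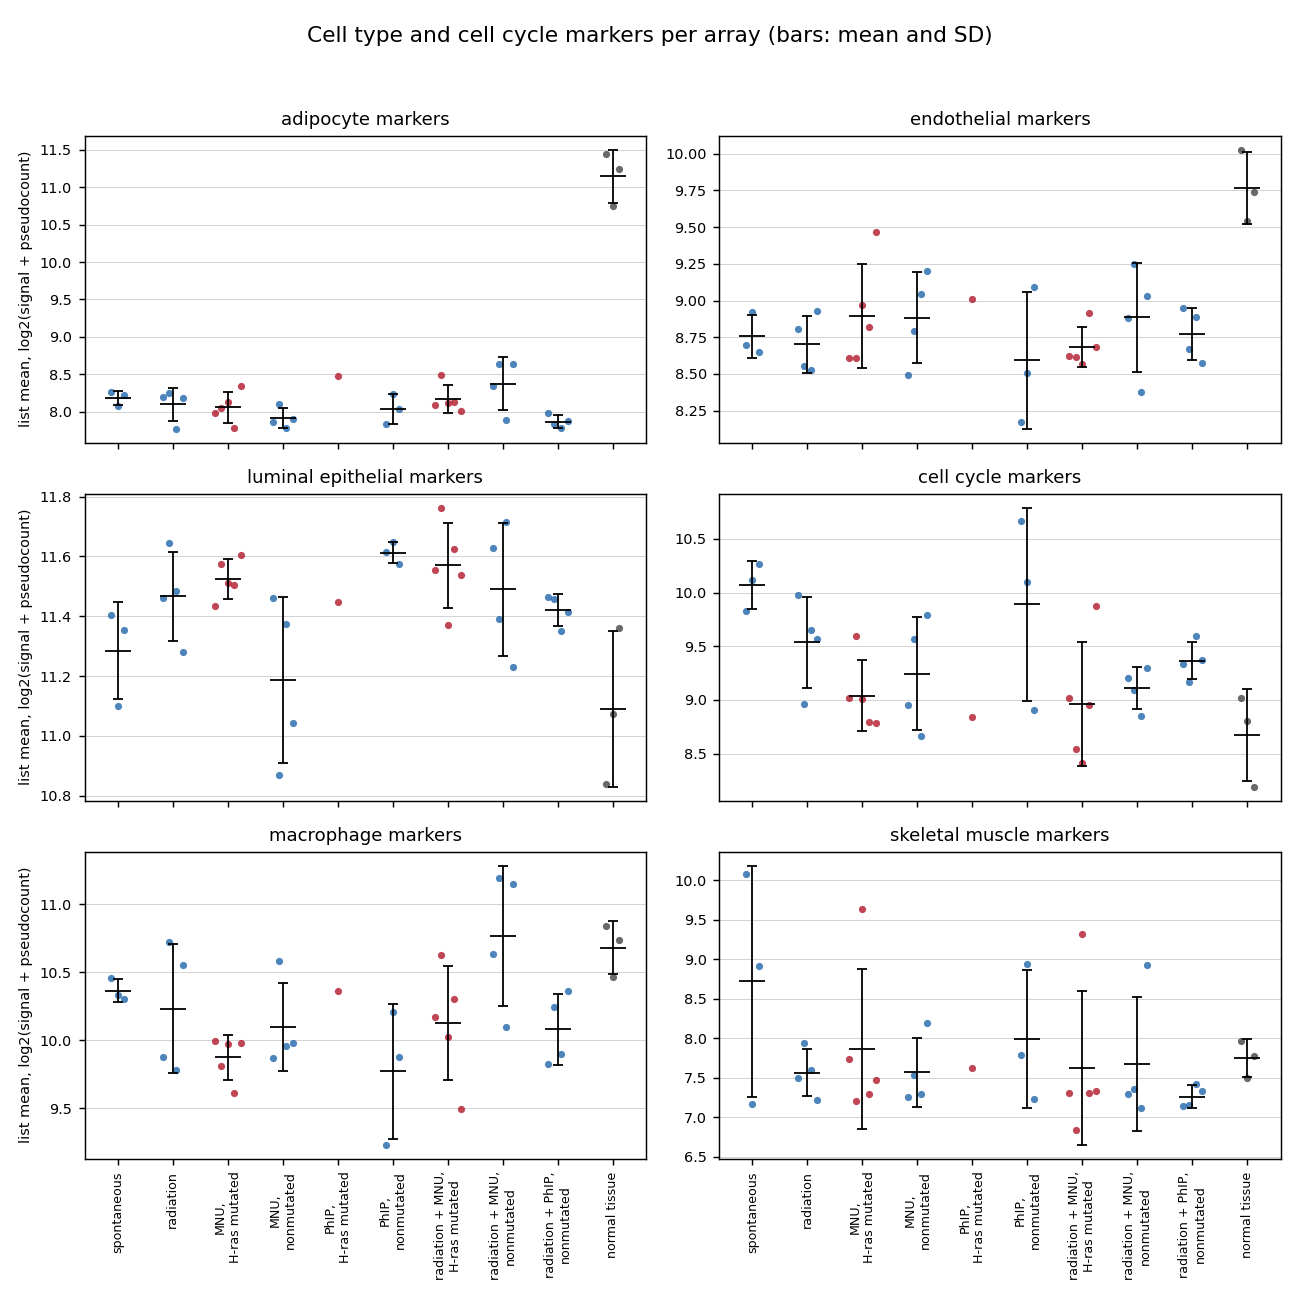
Each point is the mean log2(intensity + 42.8) of the markers of a list on 1 array, by group, for adipocyte, endothelial, luminal epithelial, cell cycle, macrophage and skeletal muscle lists, with bars for mean and SD. Red marks H-ras mutated cancers, blue nonmutated cancers and grey normal tissue, whose adipocyte mean of 11.14 lies above those of all cancer groups.

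All 3 normal tissues carried weight in this comparison. The array of normal tissue 3 stood apart, with a signal ceiling of 14.30, where normal tissues 1 and 2 had 13.69 and 13.79. Its highest intensity was 32544, against 18611 and 18771. Without normal tissue 2 the count of genes was 2734, without normal tissue 3 it was 2736, and without normal tissue 1 it was 3281. Without normal tissue 3 the luminal list passed (adjusted p = 0.00885) and the cell cycle (0.0696), macrophage (0.0662), milk (0.0768) and brown fat (0.0696) lists did not. Without normal tissue 1 the macrophage (0.0949) and brown fat (0.0749) lists did not pass. With quantile normalization the luminal list passed (0.00691) and the milk list did not (0.107). The luminal list, at 0.0534, lay near the threshold and also passed with no filter (0.0268), with the replicate block (0.042), with the signal ceiling as a covariate (0.0482) and without spontaneous cancer 2 or 3 (0.0406 and 0.0475). It passed as well without radiation 4 (0.048), MNU nonmutated 2 (0.036), radiation plus MNU mutated 3 (0.0444), radiation plus MNU nonmutated 4 (0.0443) or radiation plus PhIP 1 or 3 (0.0497 and 0.0483). The B and plasma cell list passed without radiation plus PhIP 1 (0.0238). The brown fat list did not pass with no filter (0.353).

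The next comparison asked whether cancers with an H-ras mutation differ from those without one after MNU, with or without radiation (10 mutated and 8 nonmutated cancers). No gene passed the threshold with limma, and 886 genes had an unadjusted p under 0.05. The smallest adjusted p, 0.0991, was shared by 3 genes. Ifgga2l1 measured 9.10 ± 0.58 (SD, n = 10) in mutated and 10.25 ± 0.24 (SD, n = 8) in nonmutated cancers, a difference of −1.15 ± 0.22 (SE), with all 10 mutated cancers below every nonmutated one. Prkch, a protein kinase C, measured 10.18 and 9.48 (0.70 ± 0.14, all 10 above every nonmutated cancer). Camk2b, a calcium-dependent kinase, measured 7.88 and 8.78 (−0.89 ± 0.18, 9 of 10 below every nonmutated cancer).

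No member of any list passed over all genes. Macrophage markers had lower values in mutated cancers for all 12 members, such as Cd68 (9.63 against 10.25, −0.62 ± 0.22), C1qa (−0.57 ± 0.23), Tyrobp (−0.44 ± 0.17) and Fcgr3a (−0.36 ± 0.12). The list passed with camera (adjusted p = 1.94e-07) but not with an estimated correlation (adjusted p = 0.24 with an estimated correlation). The difference of the list means was −0.433, with p = 0.028 in an exact two-sided permutation test over 15876 arrangements and 0.268 adjusted over the lists. Luminal markers had higher values for 12 of 14 members, with Gata3 (0.48 ± 0.13) and Spdef (0.87 ± 0.30) past the threshold adjusted over the list alone (2 higher, 0 lower). Their camera adjusted p was 0.00187, with adjusted p = 0.24 with an estimated correlation and 0.268 by exact permutation, adjusted over the lists. The exact permutation p-values of the lists that follow are adjusted in the same way. Most of the luminal difference lay in MNU alone, with list means of 11.53 in mutated and 11.19 in nonmutated cancers. After radiation plus MNU the luminal means were 11.57 and 11.49. Fatty acid synthesis had 1 higher, Elovl6 (0.49 ± 0.19), and 2 lower, Scd (−1.20 ± 0.44) and Fasn (−0.48 ± 0.18), adjusted over the list alone. It passed with camera (adjusted p = 0.0261, and adjusted p = 0.553 with an estimated correlation; 0.291 by exact permutation). That call was lost without MNU mutated 3 (0.0692), MNU nonmutated 2 (0.117), radiation plus MNU mutated 1 or 3 (0.0612 and 0.0605) or radiation plus MNU nonmutated 1 or 4 (0.0621 and 0.0964). It was also lost with the signal ceiling as a covariate (0.153) or a block (0.061). The mesenchymal transition list had 0 higher and 1 lower adjusted over the list alone.

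Fibroblast and matrix genes had lower values in mutated cancers for 14 of 15 members (adjusted p = 0.00187 with camera, and adjusted p = 0.614 with an estimated correlation; 0.291 by exact permutation). The interferon list did so for 10 of 13 (adjusted p = 0.00586, and adjusted p = 0.614 with an estimated correlation; 0.49 by exact permutation). Values were also lower for 20 of 23 cell cycle genes (adjusted p = 0.0158, and adjusted p = 0.798 with an estimated correlation; 0.601 by exact permutation) and for 11 of 11 T and NK cell markers (adjusted p = 0.0417, and adjusted p = 0.706 with an estimated correlation; 0.592 by exact permutation). RAS-MAPK output, the pathway downstream of H-ras, had a list mean difference of 0.019 (adjusted p = 0.723 with camera; 0.868 by exact permutation), with Spry4 at 0.18 ± 0.10 and Tgfa at 0.25 ± 0.18. The other lists had camera adjusted p of 0.0669 or more. Nearly all of the fibroblast and matrix difference lay in radiation plus MNU, with list means of 10.67 in mutated and 11.30 in nonmutated cancers. After MNU alone they were 11.04 and 11.07. The array MNU nonmutated 4, on the nonmutated side, had the lowest RNA quality, with a 3'/5' signal ratio of 12.3 for hexokinase, and without it the macrophage difference was −0.453. Without that array the milk (adjusted p = 0.00365), hormone response (0.0379), xenobiotic metabolism (0.0461), cholesterol synthesis (0.0298) and B and plasma cell (0.0461) lists passed with camera at the preset correlation. Its milk list mean was 9.84, where the other MNU nonmutated cancers had 12.16 to 12.59 and the MNU mutated ones a mean of 11.51. Milk genes were thus lower in MNU mutated cancers once it was left out. The estimated correlation was not tried without that array. With all arrays, no list passed for H-ras at the estimated correlation.

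Calls of 3 of these lists rested on single arrays. The T and NK cell list did not pass without MNU mutated 1 or 2 (adjusted p = 0.0753 and 0.104), MNU nonmutated 1, 2 or 3 (0.128, 0.411 and 0.067), radiation plus MNU mutated 1 or 3 (0.131 and 0.143) or radiation plus MNU nonmutated 2 or 4 (0.0642 and 0.384). The cell cycle list did not pass without MNU mutated 5 (0.0639), MNU nonmutated 2 or 4 (0.117 and 0.283), radiation plus MNU mutated 2 or 3 (0.109 and 0.158) or radiation plus MNU nonmutated 4 (0.0727). The interferon list did not pass without radiation plus MNU nonmutated 4 (0.0951). With the signal ceiling as a covariate or a block neither the T and NK cell list (0.161 and 0.177) nor the interferon list (0.0646 and 0.052) passed.

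Within MNU alone (5 mutated, 4 nonmutated) no gene passed with limma, and 923 had an unadjusted p under 0.05. The smallest adjusted p was 0.0662, for Prkch (0.99 ± 0.20), Nod1, a sensor of bacterial cell walls (0.64 ± 0.13), and Stat5a, which carries prolactin signals (−0.80 ± 0.16), each with all 5 mutated cancers beyond every nonmutated one. Within radiation plus MNU (5 and 4) no gene passed with limma either (460 at an unadjusted p under 0.05). The smallest p-values were those of Gpnmb, a glycoprotein of macrophages and other cells (−1.68 ± 0.34), Camk2b (−1.21 ± 0.25; both adjusted p = 0.209) and Art3 (1.17 ± 0.26, adjusted p = 0.365). The test of the difference between these H-ras effects gave no gene with limma (391 at an unadjusted p under 0.05), with Hpgd at 4.01 ± 0.94, the beta globin Hbb at −2.85 ± 0.72 and Nod1 at −0.80 ± 0.19 (all adjusted p = 1). Single arrays moved these counts: without radiation plus MNU nonmutated 2 the joint H-ras comparison gave 4 genes, and without MNU nonmutated 1 the MNU comparison gave 7. Among 100 splits of the same arrays for the joint comparison, 9 gave any gene and the highest count was 318.

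Cancers without the mutation were then compared by cause, over 22 cancers in 6 groups. Spontaneous cancers stood apart from the induced ones in a few genes, led by Vsnl1, a neuronal calcium sensor. It measured 9.80 ± 1.42 (SD, n = 3) in the spontaneous cancers and 7.22 ± 0.57 (SD, n = 19) in the others, and was the single gene past the threshold in the F test (F = 13.7, limma adjusted p = 0.00759; 1042 genes at an unadjusted p under 0.05). All 3 spontaneous cancers lay above each of the other 19 (8.82 or more against 8.70 or less). The secreted hormone Stc1 (10.59 ± 0.76), the receptor Gpr37 (11.46 ± 0.22) and the receptor tyrosine phosphatase Ptprd (9.62 ± 0.40) were also highest there (SD, n = 3).

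Against the spontaneous cancers, radiation-only cancers (n = 4) had 3 genes past the threshold with limma, all lower: Vsnl1 (−2.98 ± 0.41, adjusted p = 0.000684), Stc1 (−1.44 ± 0.26) and Gpr37 (−1.38 ± 0.26; both adjusted p = 0.037). MNU nonmutated cancers (n = 4) had 5, all lower: Vsnl1 (−2.11 ± 0.41, adjusted p = 0.0492), Ptprd (−1.86 ± 0.32, adjusted p = 0.0128), Stc1 (−1.74 ± 0.26, adjusted p = 0.00373), Gpr37 (−1.62 ± 0.26, adjusted p = 0.00454) and the phosphatase subunit Ppp2r5d (−0.54 ± 0.11, adjusted p = 0.0492). PhIP nonmutated cancers (n = 3) had 1, Vsnl1 (−2.85 ± 0.44, adjusted p = 0.00534). Radiation plus MNU nonmutated cancers (n = 4) had 9, all at adjusted p = 0.0394: the fat lipase Pnpla2 rose by 1.18 ± 0.24. The others fell, namely Vsnl1 (−2.14 ± 0.41), the sulfotransferase Chst8 (−1.67 ± 0.33), the odorant binding protein Obp3 (−1.64 ± 0.33), Ptprd (−1.61 ± 0.32), Stc1 (−1.37 ± 0.26), Gpr37 (−1.34 ± 0.26), Camta1 (−0.91 ± 0.18) and Prss56 (−0.69 ± 0.14). Radiation plus PhIP cancers (n = 4) had 3, all lower: the plasmin precursor Plg (−3.22 ± 0.55, adjusted p = 0.0089), Vsnl1 (−2.86 ± 0.41, adjusted p = 0.00144) and Ptprd (−2.05 ± 0.32, adjusted p = 0.00393). In every one of these calls, each induced cancer lay beyond all 3 spontaneous ones. Without spontaneous cancer 2 the counts for radiation, MNU, PhIP and radiation plus MNU were 1, 2, 0 and 0, and without spontaneous cancer 1 that for radiation plus MNU was 0. Without spontaneous cancer 3 the counts were 6 for radiation, 3 for PhIP, 4 for radiation plus MNU and 8 for radiation plus PhIP.

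Several of these calls depended on the processing. All 9 calls of radiation plus MNU, Vsnl1 and Gpr37 included, were lost with the added constant at the 5th percentile, with all filtered probe sets, with the mean of a gene's probe sets and with the replicate block. They were also lost in a fit of only the groups compared and with the signal ceiling as a covariate or a block. In the fit of only the groups compared, all 3 calls of radiation, all 5 of MNU and the call of Vsnl1 for PhIP were lost too, radiation then giving Plg and Sytl2, and 2 of the 3 calls of radiation plus PhIP remained. With the ceiling as a block none of the 3 calls of radiation remained, and Vsnl1 was lost for PhIP. Among the 5 calls of MNU, Ptprd and Stc1 remained with that block, and Ptprd was left of the 3 calls of radiation plus PhIP.

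**Figure D3:**
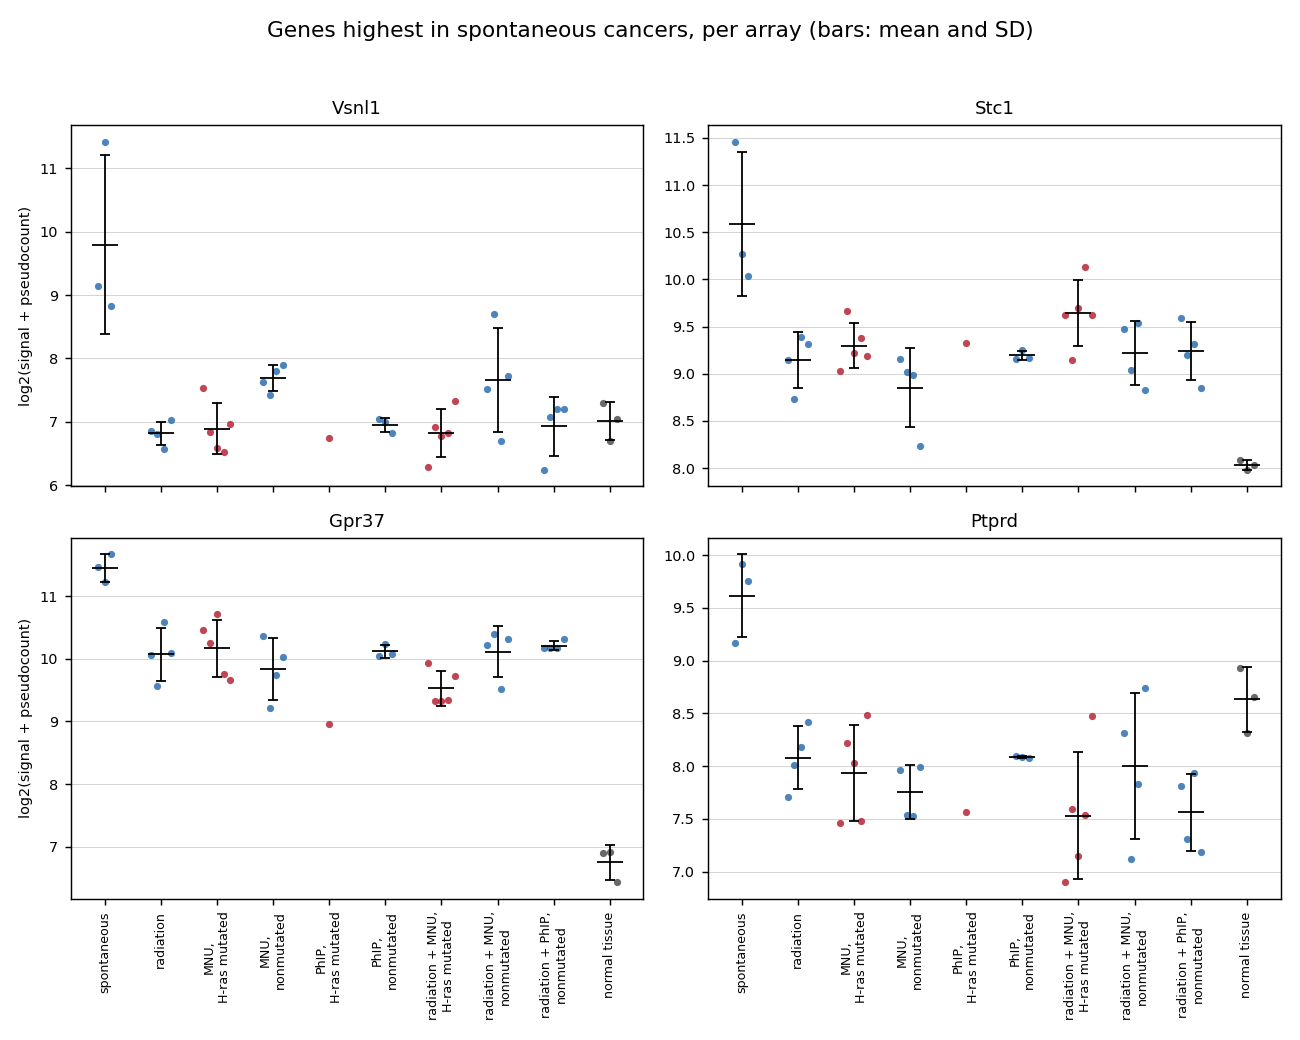
Points give log2(intensity + 42.8) of Vsnl1, Stc1, Gpr37 and Ptprd on each array, by group, with bars for mean and SD; red marks H-ras mutated cancers, blue nonmutated cancers and grey normal tissue. The spontaneous cancers, at 8.82 to 11.42 for Vsnl1, lie above the other 19 nonmutated cancers in all 4 panels.

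Of the 11 genes past the threshold in at least 1 of these 5 comparisons, 4 passed in at least 2, Vsnl1 in 5 and Gpr37, Ptprd and Stc1 in 3 each. The 5 comparisons share their 3 spontaneous cancers. In 100 simulated draws of unchanged groups against shared controls, 0.03 genes on average passed in at least 2 (at most 2). Genes were drawn independently there, without structure shared by arrays, so this figure can understate what real arrays give. Pairs of comparisons shared 1 to 4 genes, and independent lists would share at most 0.00382. With 3 controls no split into parts of at least 2 arrays was possible, so part of the excess may come from the shared controls.

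Pooled against all 19 induced nonmutated cancers, a contrast added after these results had been seen, spontaneous cancers differed in 8 genes with limma. Higher in them were Vsnl1 (2.57 ± 0.34, adjusted p = 0.000214), Plg (2.38 ± 0.45), Ptprd (1.73 ± 0.26), the matrix protein Edil3 (1.73 ± 0.34), Stc1 (1.46 ± 0.22), Chst8 (1.39 ± 0.27) and Gpr37 (1.39 ± 0.21), and the tRNA-modifying gene Ctu2 was lower (−0.50 ± 0.09). The adjusted p-values other than that of Vsnl1 ran from 0.00105 to 0.0271, and all 3 spontaneous cancers lay beyond the mean of the others for each gene. The spontaneous cancers also had the highest cell cycle list mean of the groups (10.07 ± 0.22, SD, n = 3), skeletal muscle markers of 8.72 ± 1.47. Their arrays had a low signal ceiling, between 13.37 and 13.56, where 27 of all arrays had 13.63 or more. With the 9 lower-ceiling arrays as a block 5 genes passed, of which Ptprd, Stc1 and Vsnl1 were among the 8, and the F test gave 0. The F test also gave 0 without spontaneous cancer 2.

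Adding radiation was asked about within each background and over all 4 of them (17 irradiated and 15 unirradiated cancers). Averaged over the backgrounds no gene passed the threshold with limma, and 1166 had an unadjusted p under 0.05. The smallest p-values were those of Dennd6a (0.40 ± 0.08, adjusted p = 0.122, 15 of 17 irradiated cancers above the mean of the others), Nherf2, a scaffold of membrane transporters (−0.45 ± 0.10), and the semaphorin Sema4b (0.47 ± 0.10; both adjusted p = 0.249). All 23 cell cycle genes had lower values in irradiated cancers, such as Birc5 (−0.41 ± 0.14) and Cdc20 (−0.58 ± 0.22). The list passed with camera (adjusted p = 2.92e-07), but adjusted p = 0.74 with an estimated correlation. Its mean differed by −0.318 (−0.53 with no chemical, −0.52 with PhIP, −0.13 in MNU nonmutated and −0.08 in MNU mutated cancers), with p = 0.0624 in a two-sided permutation test (1e+05 resamples) and 0.551 adjusted over the lists.

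Macrophage markers had higher values in irradiated cancers for 11 of 12 members, with a list mean difference of 0.275 (adjusted p = 9.03e-05 with camera, and adjusted p = 0.74 with an estimated correlation). Skeletal muscle markers had lower values for 11 of 11 (−0.505; adjusted p = 0.00255 and 0.0646 without spontaneous cancer 1, and adjusted p = 0.74 with an estimated correlation). B and plasma cell markers had higher values for 6 of 6 (0.365; adjusted p = 0.00497, and adjusted p = 0.74 with an estimated correlation). Nearly all of that difference lay in the PhIP background, with list means of 8.86 with and 7.43 without radiation, against 8.13 and 8.07 with no chemical, 7.99 and 7.97 in MNU nonmutated and 7.73 and 7.76 in MNU mutated cancers. The B and plasma cell call was lost without radiation plus PhIP 1 (0.0555) and with the signal ceiling as a covariate (0.19) or a block (0.147). The macrophage difference ran from −0.13 with no chemical to 0.67 in MNU nonmutated cancers. The skeletal muscle difference ran from −1.15 with no chemical to 0.10 in MNU nonmutated cancers. The permutation p of each of these 3 lists was 0.551 adjusted over the lists. No list member passed over all genes. Adjusted over the list alone, the hormone response list had 0 higher and 1 lower, the progesterone receptor Pgr (−0.97 ± 0.27). The B and plasma cell list had 1 higher, Blnk (0.60 ± 0.19), the adipocyte list 2 higher and 1 lower, and the cholesterol synthesis and mesenchymal transition lists 1 lower each. The p53 targets, which include genes induced by radiation damage, had a list mean difference of 0.015 (adjusted p = 0.746), and DNA repair had an adjusted p of 0.447. The samples were grown cancers rather than tissue taken just after irradiation, so the immediate response to radiation was not tested. The remaining lists had camera adjusted p of 0.0865 or more, although the T and NK cell list passed with quantile normalization (0.0353) and the fibroblast and matrix list with the ceiling block (0.0279). Among them, the mast cell list was lower with radiation in all 4 backgrounds (−0.91 with no chemical, −0.49 in MNU nonmutated, −1.22 in MNU mutated and −0.31 with PhIP). Its arrays spread widely, with SD of 0.58 to 2.00 within these groups. It passed without any 1 of several arrays, such as radiation plus MNU nonmutated 2 (camera adjusted p = 0.00233). The sign of the test and of the mean or median differed for the interferon, fibroblast and endothelial lists.

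No gene passed in the single backgrounds with limma. Radiation plus MNU against MNU gave 0 genes in nonmutated cancers (4 and 4; 927 at an unadjusted p under 0.05), with the urokinase receptor Plaur at 0.99 ± 0.21, Tmem14a at −0.95 ± 0.20 and the tight junction gene Tjp3 at 0.82 ± 0.18 (all adjusted p = 0.252). In mutated cancers (5 and 5) it also gave 0 (711 at an unadjusted p under 0.05), with Snapc4 at −0.47, C10h17orf58 at −0.64 and Cntnap2 at −0.69 (all adjusted p = 0.726). Radiation plus PhIP against PhIP (4 and 3) gave 0 genes with limma (1108 at an unadjusted p under 0.05). Lef1, a transcription factor of Wnt signalling, measured 11.31 ± 0.24 (SD, n = 4) and 9.03 ± 1.48 (SD, n = 3) there, a difference of 2.28 ± 0.43 (limma adjusted p = 0.12), with all 4 combined cancers above every PhIP cancer. It passed the threshold without the array of lowest RNA quality, MNU nonmutated 4, which adds only to the spread, and without PhIP nonmutated 4 the comparison gave 7 genes.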

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

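The test of adipocyte loss, the signal ceiling tests, the contrast of spontaneous with other nonmutated cancers and the list permutation tests were chosen only after the results were seen. The rule for the ceiling in the first pattern replaced one that had left it undecided, and was set after its values were seen.

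In 8 genes the spontaneous cancers differed from the other 19 nonmutated cancers, by a median of 1.59 on the log2 scale (median SE 0.27), and these genes were picked for that difference. Skeletal muscle in the samples is argued against as the whole cause, since with the muscle markers as a covariate 108.6% of the median change remained (1.73, SE 0.28) and 7 of 8 genes passed. A single deviating array is argued against for the 8 genes as a set. Without any 1 of the 3 arrays the median change kept at least 97.3% of its size (1.73, 1.60 and 1.55 without arrays 1, 2 and 3). Only 5, 3 and 4 genes still passed, and the median SE widened to 0.32, 0.31 and 0.32. The median does not cover each gene. Vsnl1 ran from 8.82 to 11.42 over the 3 arrays, so the size of its change leaned on the highest of them. A lower signal ceiling is argued against as the whole cause of the median change. On the 6 lower-ceiling arrays of other groups these genes differed from their groups by a median of 0.095 (SE 0.231). On the 4 of them with an H-ras mutation the median was 0.079 (SE 0.307). With the ceiling as a covariate (1.72, SE 0.30) or a block (1.66, SE 0.34) the median size remained, and 5 or 3 genes passed with the wider SE. A higher share of dividing cells was not tested as a covariate. PhIP nonmutated 2 and 3 had cell cycle list means of 10.67 and 10.10, beside 9.83 to 10.27 in the spontaneous cancers. Yet Vsnl1, Ptprd, Stc1 and Gpr37 lay below every spontaneous cancer in all 19 induced ones, and Plg narrowly so (9.66 against 9.75). Edil3, Chst8 and Ctu2 were not fully separated. The genes were picked for differing from these same 19 cancers, so their separation cannot decide whether dividing cells are a cause. The spontaneous origin and a batch of these 3 arrays alone, which could not be separated from the group, stay open, as does a higher share of dividing cells.

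The adipocyte markers were far lower in the cancers than in normal tissue. If a lower share of adipocytes were the only change, markers of every other cell type would rise alike, but the luminal list had a median change of 0.41 and the basal list 0.31, while the endothelial list had −1.03 and the macrophage list −0.61. The luminal median exceeded the endothelial one by 1.43 (SE 0.26, 10000 bootstrap draws over genes). This SE does not hold the spread between arrays. Over arrays the endothelial list mean was 8.78 ± 0.27 (SD, n = 33) in the cancers and 9.77 ± 0.24 (SD, n = 3) in normal tissue. The luminal list mean was 11.45 ± 0.19 and 11.09 ± 0.26. The difference argues against fewer adipocytes with no other change. Fewer endothelial cells and macrophages beside fewer adipocytes, or lower expression within these cells, could account for it and were not tested, and neither was a biological explanation.

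Macrophage markers were lower in H-ras mutated cancers, by −0.433 in the list mean. Poor RNA on MNU nonmutated 4 is argued against, since 104.4% of the difference remained without that array (−0.453). The list mean stood high on another array of its group, MNU nonmutated 2 (10.58, nearest 9.98), and the difference without it was not computed. After MNU the means were 9.87 in mutated and 10.10 in nonmutated cancers, and after radiation plus MNU 10.12 and 10.77. Most of the difference thus lay in radiation plus MNU. Chance in how the labels fell could not be excluded, since the exact permutation p was 0.268 after adjustment over the lists. A difference that goes with the H-ras mutation may exist and stays open.

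The splits of the same arrays below were each taken alone, and adjusted over the 16 comparisons (Benjamini-Hochberg) the smallest share was 0.12, with 100 splits drawn at most. The cancers against normal tissue had 4045 genes, and any other of the 100 splits drawn had at most 1071 (1 of 100 as large). The split with 1071 kept 2 normal tissues on one side. Taken alone this share (0.01), the smallest that 100 splits can give, lies under 0.05. Adjusted over the 16 comparisons it is 0.12, so the splits by themselves do not exclude chance, though 4045 lies far above 1071. The splits decide nothing for spontaneous against the other nonmutated cancers (8 genes, 3 of 100 splits as large, the real one included), since that contrast was chosen after the spontaneous cancers were seen to stand apart. Its highest other split gave 66 genes and the median was 0, and whether the 3 arrays of that highest split share a structure was not tested. For radiation plus MNU against spontaneous (9 genes, highest other 1) and radiation plus PhIP against spontaneous (3 genes, highest other 0), 1 of 35 splits was as large, the smallest share that 35 splits can give. Taken alone these shares (0.029) lie under 0.05, but adjusted over the 16 comparisons they are 0.12, so chance is not excluded. Radiation plus MNU, though, rests on a count that fell to 0 without any of several arrays. Chance cannot be excluded for the F test over etiologies (1 gene, 18 of 100 splits, highest other 14) or for radiation against spontaneous (3 genes, 4 of 35, highest other 6). For MNU against spontaneous the share was 2 of 35 with 5 genes and a highest other of 5, so chance cannot be excluded there either. For PhIP against spontaneous the 10 splits are too few (1 gene, 1 of 10, highest other 0).

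Where no gene passed, every split gave as many. The highest other splits were 318 genes for H-ras, 376 within MNU, 324 within radiation plus MNU and 394 for the interaction (100 of 100 splits each). Most splits gave none: any gene passed in 9, 13, 13 and 4 of them, and the median was 0, so the few large counts point at most to a structure shared by some arrays. Arrays of lower signal ceiling lay mostly on one side in these highest splits: 5 of 6 in the splits with 318 and 394 genes, 3 of 4 in that with 376 and 2 of 2 in that with 324. With the ceiling as a block the H-ras comparisons gave 0 genes. Split by ceiling alone, though, the MNU cancers gave 1 gene, so the ceiling alone does not account for the 376. In the split with 376 genes, MNU mutated 1, 2 and 3 and MNU nonmutated 4 lay on 1 side. Their mast cell list means were 9.92 to 11.26, and those of the other MNU cancers at most 9.32. A part played by mast cells was not tested. The highest other splits were 4 genes for radiation plus MNU against MNU in nonmutated cancers (35 of 35 splits), 1 in mutated cancers (100 of 100), 2 for radiation plus PhIP against PhIP (35 of 35) and 7 for radiation averaged (100 of 100).

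Single arrays stood far from the rest of their group, in 5 of 30 tests of array measures, 8 of 42 of list means and 10 of 100 of gene values, where chance gives about 1 in 20 (1.5, 2.1 and 5). The array MNU nonmutated 4 had a GAPDH 3'/5' ratio of 1.56 (nearest 1.06), a hexokinase ratio of 12.3 (nearest 2.48) and a signal ceiling of 13.27 (nearest 13.75). The GAPDH ratio of radiation plus MNU mutated 1 was 1.05 (nearest 0.996), and the hexokinase ratio of MNU mutated 1 was 4.66 (nearest 2.55). The adipocyte list mean was 7.77 in radiation 3 (nearest 8.18) and 8.49 in radiation plus MNU mutated 2 (nearest 8.13). The macrophage list mean was 10.58 in MNU nonmutated 2 (nearest 9.98). Skeletal muscle markers averaged 9.64 in MNU mutated 3 (nearest 7.74), 9.32 in radiation plus MNU mutated 3 (nearest 7.34) and 8.93 in radiation plus MNU nonmutated 4 (nearest 7.36). Mast cell markers averaged 11.26 in radiation plus MNU nonmutated 2 (nearest 7.61) and 10.09 in radiation plus PhIP 4 (nearest 7.52).

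Among gene values, MNU nonmutated 4 had Plaur at 6.06 (nearest 7.23) and Tjp3 at 7.86 (nearest 8.25). MNU mutated 4 had Stat5a at 11.4 (nearest 10.93) and MNU mutated 1 had Cntnap2 at 8.8 (nearest 7.98). Radiation plus MNU mutated 4 had Hbb at 12.18 (nearest 10.36) and radiation plus MNU mutated 5 had Sema4b at 8.92 (nearest 9.91). Radiation plus MNU nonmutated 3 had Nherf2 at 7.94 (nearest 7.64). Radiation plus PhIP 1 had Vsnl1 at 6.24 (nearest 7.08) and Fam107b at 10.94 (nearest 10.32), and radiation plus PhIP 4 had Gpr37 at 10.32 (nearest 10.18).

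The H-ras effect differed between MNU and radiation plus MNU in 3 lists with camera at the preset correlation. The basal and myoepithelial list changed by −0.16 with MNU and 0.27 with radiation plus MNU (interaction adjusted p = 0.00228, and adjusted p = 0.583 with an estimated correlation). The fibroblast and matrix list changed by −0.02 and −0.63 (adjusted p = 0.000525, and adjusted p = 0.583 with an estimated correlation). The macrophage list changed by −0.22 and −0.64 (adjusted p = 0.0136, and adjusted p = 0.619 with an estimated correlation).

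Probe sets with no gene symbol (5218) or several (365) were outside the comparisons. In the cancers against normal tissue 1346 of these 5583 passed with limma, 773 higher and 573 lower in the cancers, and 214 and 154 of them changed at least 2-fold.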

How the results depend on the processing

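Leaving out the array of lowest RNA quality and fitting the signal ceiling as a covariate or a block were chosen only after the results were seen. No named gene or list that passed the threshold, in the main fit or in a setting, reversed its direction. Signs were not compared where neither passed, nor for the F test. For the 33 cancers against normal tissue, no setting moved the count of 4045 genes by more than 1.5 times, and the share higher in the cancers, 52.4%, ran from 48.8% to 57%. Quantile normalization moved the median change of all genes from 0.024 to 0.005. Of the named gene values, 41 passed newly, 292 lost their call and 12997 kept their side of the threshold. Of the list values, 58 passed newly, 66 lost their call and 2679 kept their side. For the cancers against normal tissue, the RAS-MAPK, p53, fatty acid and endothelial lists lost their call only with the estimated correlation, and the milk and brown fat lists lost it also with the ceiling as a covariate (adjusted p = 0.35 and 0.0563) or a block (0.0615 and 0.0519). The hormone response list passed with the ceiling covariate (0.0487). For H-ras, the T and NK cell list also lost its call with the stricter filter (0.225) and the constant at the 5th percentile (0.0705), and the cholesterol list passed with only the groups compared (0.0281). Leaving out single arrays also moved calls of the hormone response, xenobiotic, cholesterol and mast cell lists for H-ras and of the milk, cholesterol, fibroblast, T and NK cell and mast cell lists for radiation past the threshold. Except where stated, the cause of the changes below was not tested.

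Counts that moved over 1.5 times were these. Quantile normalization moved radiation plus PhIP against spontaneous from 3 to 5. With no filter, MNU against spontaneous went from 5 to 3. The stricter filter moved the F test over etiologies from 1 to 5 (Gpr37, Plg, Ptprd, Stc1 and Vsnl1), and the trended robust variance also gave 5. The added constant at the 5th percentile gave 1 gene for radiation (main 3), 3 for MNU (main 5), 0 for radiation plus MNU (main 9) and 5 for spontaneous against the other nonmutated cancers (main 8). At the 40th percentile the F test gave 5, radiation against spontaneous 6 and radiation plus PhIP against spontaneous 6. All filtered probe sets gave 1 for H-ras within MNU (main 0), 2 for the F test, 6 for radiation and 0 for radiation plus MNU. The mean of a gene's probe sets gave 1 for H-ras within MNU (Prkch), 2 for MNU against spontaneous and 0 for radiation plus MNU. A fit of only the groups compared, which has fewer arrays to estimate the spread, gave 2 for H-ras within MNU (Plxna3 and Stx1a), 0 for the F test and 0 each for MNU, PhIP and radiation plus MNU against spontaneous. For radiation against spontaneous it gave 2 (Plg and Sytl2), neither among the 3. It also gave 27 for radiation plus PhIP against spontaneous, 1 for radiation plus PhIP against PhIP (Padi3) and 5 for spontaneous against the others. Without the array of lowest RNA quality, MNU against spontaneous gave 3, radiation plus PhIP against spontaneous 6 and radiation plus PhIP against PhIP 1 (Lef1). The ceiling covariate gave 0 for the F test, 0 for PhIP, 0 for radiation plus MNU and 2 for radiation plus PhIP against PhIP (Lef1 and Mycn). Lower-ceiling arrays as a block gave 0 for the F test, 1 for radiation (Prtg, not among the 3), 2 for MNU (Ptprd and Stc1), 0 for PhIP, 0 for radiation plus MNU and 5 for spontaneous against the others.

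The replicate numbers did not pair the arrays: 122 pairs with the same number had a mean correlation of deviations of 0 (−0.498 to 0.394), 420 pairs with different numbers 0.001, and 7 of 35 arrays lay closest to their own number. As a block they gave 2 for the F test, 5 for radiation, 0 for radiation plus MNU, 1 for radiation averaged (Dennd6a) and 5 for spontaneous against the others, and moved no other count by over 1.5 times.

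With each array left out in turn, the cancers against normal tissue gave 2734 to 4260 genes. H-ras gave 0 to 4 (2 without MNU nonmutated 1, 4 without radiation plus MNU nonmutated 2), and H-ras within MNU 0 to 7 (1 without MNU mutated 2, 4 without MNU mutated 4, 7 without MNU nonmutated 1). H-ras within radiation plus MNU gave 0 to 2 (2 without radiation plus MNU nonmutated 2) and the interaction 0 to 1 (1 without MNU nonmutated 1). The F test gave 0 to 8: 0 without spontaneous 2, 3 without spontaneous 3, 7 and 2 without radiation 1 and 4, 8 and 2 without MNU nonmutated 1 and 3, 5 without PhIP nonmutated 4, and 3, 4 and 4 without radiation plus MNU nonmutated 2, 3 and 4. Against spontaneous cancers, radiation gave 1 to 6 (1 without spontaneous 2, radiation 2 or radiation 4, 6 without spontaneous 3), and MNU 2 to 8 (2 without spontaneous 2 or MNU nonmutated 2, 3 without MNU nonmutated 4, 8 without MNU nonmutated 1). PhIP gave 0 to 3 (0 without spontaneous 2 or PhIP nonmutated 4, 3 without spontaneous 3). Radiation plus MNU gave 0 to 4 (0 without spontaneous 1 or 2 or radiation plus MNU nonmutated 1, 3 or 4, 2 without its array 2, 4 without spontaneous 3). Radiation plus PhIP gave 2 to 8 (8 without spontaneous 3). Radiation plus MNU against MNU gave 0 to 1 in nonmutated cancers (1 without radiation plus MNU nonmutated 2) and 0 to 0 in mutated ones. Radiation plus PhIP against PhIP gave 0 to 7 (7 without PhIP nonmutated 4). Radiation averaged gave 0 to 3 (1 without spontaneous 2 or radiation 1, 3 without radiation plus MNU mutated 5). Spontaneous against the others gave 4 to 11 (5 without spontaneous 1, 4 without spontaneous 2). Signal over background limits the weakly expressed genes, whose changes shrink with the added constant and which the filter removes.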

Other observations

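The genes, samples and signal ceiling tests below were all chosen after the data had been seen. The growth factor gene Fgf3 was high in 7 cancers and at most 5.98 on every other array, normal tissue included. It measured 9.56 and 9.77 in spontaneous cancers 1 and 3, 10.83 in PhIP nonmutated 3, 7.31 in PhIP nonmutated 2, and 10.11, 11.31 and 9.88 in radiation plus MNU nonmutated 1, 3 and 4. None of these cancers carried an H-ras mutation, but Fgf3 did not pass the threshold for H-ras (−1.80 ± 0.59, limma adjusted p = 0.43) or in the F test over etiologies (adjusted p = 0.199). The imprinted growth genes Igf2 (6.15 to 13.74) and H19 (7.58 to 13.74) also varied widely between arrays. In the spontaneous cancers Igf2 measured 13.11 ± 0.13 (SD, n = 3) and in normal tissue 8.88 ± 0.22 (SD, n = 3), and over all cancers against normal tissue it did not pass (2.47 ± 1.01, limma adjusted p = 0.0581).

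Cell type markers varied within groups. The cancer PhIP nonmutated 2 had the lowest fibroblast and matrix list mean of all arrays, 8.97, and the highest cell cycle list mean, 10.67. The B and plasma cell list mean of radiation plus PhIP 1 was 9.98. Arrays with a lower signal ceiling were found in 5 groups, and within the 4 groups that held both kinds 644 genes differed between them with limma, 270 of them higher in the lower-ceiling arrays (2700 genes at an unadjusted p under 0.05). Within the 9 MNU cancers alone, 4 lower-ceiling arrays against 5 others gave 1 gene. Lower-ceiling arrays of these groups included MNU mutated 1 and MNU nonmutated 4, with hexokinase 3'/5' ratios of 4.66 and 12.3. Both, and MNU mutated 2 and radiation plus MNU nonmutated 2, had mast cell list means of 9.92 or more. MNU mutated 5 (7.94) and radiation plus MNU mutated 1 (8.72) did not. RNA quality and cell content were thus not separated from the ceiling. The labels give no batch or date, so whether the ceiling reflects the arrays or the samples was not tested.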
